A study of Homo sapiens with 6 samples.

How the data were processed

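RNA from 6 samples of the A2780 cell line was measured, 3 labelled control and 3 labelled as treated with 10 µM lycorine for 24 h. Per the labels' protocols, total RNA was extracted with TRIzol, polyadenylated RNA was taken with oligo-dT beads and fragmented, and cDNA was primed with random hexamers. No strand-marking step is described there, and the labels do not say what the control cells received in place of lycorine.

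The authors deposited 1 table of FPKM values with 58735 genes and a column for each library, matched to the samples by the library names in the labels. Per the submitters' processing notes, which give no roles or order, the tools were FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.10b, featureCounts, Subread 2.0.3 and DESeq2 1.30.1, with the genome build GRCh38.p13. The annotation release, the strand setting, the treatment of reads with several alignments and the rule for the library total are not given in the sources used here. Chromosome, start and end of 58690 of the 58735 gene IDs were identical to those of GENCODE 29 on GRCh38, and coordinates are printed as the deposited table gives them. For 27 genes the symbol had been stored as a date, and all 27 were restored by gene ID.

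Whether whole reads lie behind the deposited FPKM was tested by multiplying each value by the gene length of the same table. In every library 100% of the values above 0 were whole multiples of 1 step, within a tolerance of 0.05 of a step, and these multiples were taken as reads. They summed to between 32349332 and 35853934 per library. The library total implied by the step was 1.03 to 1.04 times this sum in control libraries and 0.981 to 0.998 times in lycorine libraries, so the deposited scale was not that of the recovered reads alone. With 3 reads as the floor, a count of 0 in a library allows up to 0.0837 to 0.0927 CPM. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Pairs of libraries within a group were compared by a chi-square of reads over genes with at least 20 reads in the pair.

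Genes with a mean FPKM of at least 1 over all 6 libraries were tested, 13730 in all. Values were transformed as log2(FPKM + 1), with a pseudocount of 1, and lycorine was compared with control by limma 3.58.1 in R 4.3.3, with a trend of variance on mean level and two-sided moderated tests. Adjusted p-values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05, and a change of at least 1 on the log2 scale was counted as at least 2-fold. Single values per library were compared with an exact permutation test. Since FPKM values are not counts, no count model was used for the main result.

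Before the data were examined, 36 gene lists were fixed, of pathways, cell states, markers of the tissue and markers of immune, endothelial and fibroblast cells. The 33 lists with at least 5 tested members were tested by camera with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Counts of members are given over all genes tested and adjusted over the list alone. The genes named in the text were taken by a rule fixed at the same time. It names the 12 largest rises and 12 largest falls of protein-coding genes past the threshold whose groups do not overlap. It takes from each list up to 4 members with the smallest adjusted p in the list's direction and up to 2 in the other. Besides some genes that are not reported here, it always names PIK3CA, AKT1, AKT2, MTOR, SOX2, POU5F1, NANOG, KLF4, MYC, ALDH1A1, PROM1, CD44, CD24, KIT, BMI1, CCND1, CDKN1A, MKI67, BCL2, MCL1, DDIT3 and ATF4. Of the 224 genes so taken 219 were tested, 215 passed, and for 214 of these the groups did not overlap. Exons shared with another expressed gene were looked up in GENCODE 29 and are named where a value is printed.

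Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a minimum mean FPKM of 5, scaling by median ratios, quantile normalization, limma without the trend, protein-coding genes alone, the replicate number as a block, each library left out in turn, camera with an estimated correlation and fry. After the data had been seen, 3 were added, namely limma-voom on the recovered reads, the library total taken over nuclear genes alone, and removal of the trend with gene length and GC content (splines with 5 degrees of freedom) from each library. GC content was computed from the GENCODE 29 transcripts. Intervals of medians in the closing part are 95% bootstrap intervals over genes from 2000 resamples.

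The procedure was tested on simulated data made for the comparison of lycorine with control. Reads for the 13730 tested genes were drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 1.5-fold, in 2 simulations. The one run first gave all genes 1 dispersion, the median of the real genes (0.00147). Limma on log2(FPKM + 1) then recovered 94 of the 100 genes changed 2-fold and 77 of those changed 1.5-fold, and called 31 unchanged genes, 15.3% of its calls, where 5% was aimed at. After this result had been seen, a simulation with dispersions that differ between genes as in the real reads was added. There limma recovered 92 and 89 and called 16 unchanged genes, 8.12% of its calls, still above 5%. Genes shorter than 1000 bases, 1430 of the 13730, held 21 of the 31 and 8 of the 16 wrong calls. They have fewer reads at a given FPKM than longer genes. The test was left as fixed in advance. For limma on log2(FPKM + 1) the simulated reads were scaled by the deposited library totals, not by the read sums they were drawn from. Those totals lay above the sums in control and below them in lycorine libraries, so unchanged genes carried a small built-in rise. The shares of wrong calls mix this shift with errors of the test. They also hold only for data in which few genes change. Limma-voom used the read sums and carried no such shift, so its lower shares are no like comparison. Limma-voom on the simulated reads recovered 97 and 85 in the simulation run first, with 8 unchanged genes or 4.21% of its calls, and 94 and 94 in the other, with 8 or 4.08%. In the simulation with differing dispersions, the median fitted change of the genes changed 2-fold was 0.86 by limma on log2(FPKM + 1), below the true value of 1 because of the pseudocount, and 1.00 by limma-voom. In both, camera called a list of changed genes and 0 of 30 lists of unchanged genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.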

Results

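Messenger RNA was measured in A2780, an established human ovarian adenocarcinoma cell line, after 24 h with 10 µM lycorine, an alkaloid of plants of the Amaryllidaceae family, and in control cells of the same line. The series asks how lycorine bears on the growth and the stem-like properties of ovarian cancer cells, with signalling through PI3K and AKT as the pathway in question. Each group held 3 libraries. Gene levels are given as FPKM (fragments scaled to the length of the gene and the size of the library), as mean ± SD with n = 3 libraries per group, and coordinates refer to GRCh38. The reads recovered from the FPKM values came to between 32349332 and 35853934 per library. Libraries of one group correlated with Pearson's r between 0.991 and 0.992 across genes on the log2 scale, where genes are not independent replicates. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom between 4.41 and 6.41. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

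The control and lycorine libraries stood far apart. The first principal component of the log2 values carried 94.0% of the variance and separated the groups, and the second carried 1.59%. Control libraries had 14005 ± 85.4 genes at an FPKM of 1 or more, against 13161 ± 20.03 with lycorine. The 10 most abundant genes took 7.57% ± 0.152 of the reads in control cells and 3.48% ± 0.0239 with lycorine, and genes of the mitochondrial genome took 4.93% ± 0.176 and 1.92% ± 0.0300. In each of these measures the groups did not overlap, and an exact two-sided permutation test gave p = 0.10, the smallest that 3 against 3 allow.

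Most expressed genes differed between the groups. Of 13730 genes with a mean FPKM of at least 1, 11391 (83.0%) passed limma with Benjamini-Hochberg adjustment at 0.05, 6336 of them higher and 5055 lower with lycorine. A change of at least 2-fold as well was found for 3554 genes, 1895 higher and 1659 lower, and at least 4-fold for 180 higher and 303 lower. The balance of all calls turned to 5669 higher and 5715 lower with median ratios, and to 7145 and 7720 without the filter, where more genes were tested. The balance of the 2-fold changes turned under several alternatives, to 1540 higher and 1925 lower with median ratios, 1646 and 1752 after quantile normalization, 1650 and 1895 with the library total over nuclear genes, 1507 and 1522 with protein-coding genes alone, and 2409 and 2463 by limma-voom on the recovered reads, which differs in its library total and weights as well. Changes of at least 4-fold came to 452 higher and 784 lower with a pseudocount of 0.1, and to 460 and 906 by limma-voom. Log2 changes and the 2-fold and 4-fold counts are differences of log2(FPKM + 1), which understate the change of low genes, and a fold printed for a single gene is the ratio of its group means of FPKM. The median change over all tested genes was 0.09, and scaling the libraries by median ratios moved it to -0.01, so that the changes of gene lists below are to be read against a median of 0.09. The groups did not overlap for 11249 of the genes past the threshold, where chance gives 10% of genes. With a minimum mean FPKM of 5 the test covered fewer genes, and 7041 passed, of which 2207 changed at least 2-fold.

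**Figure D1:**
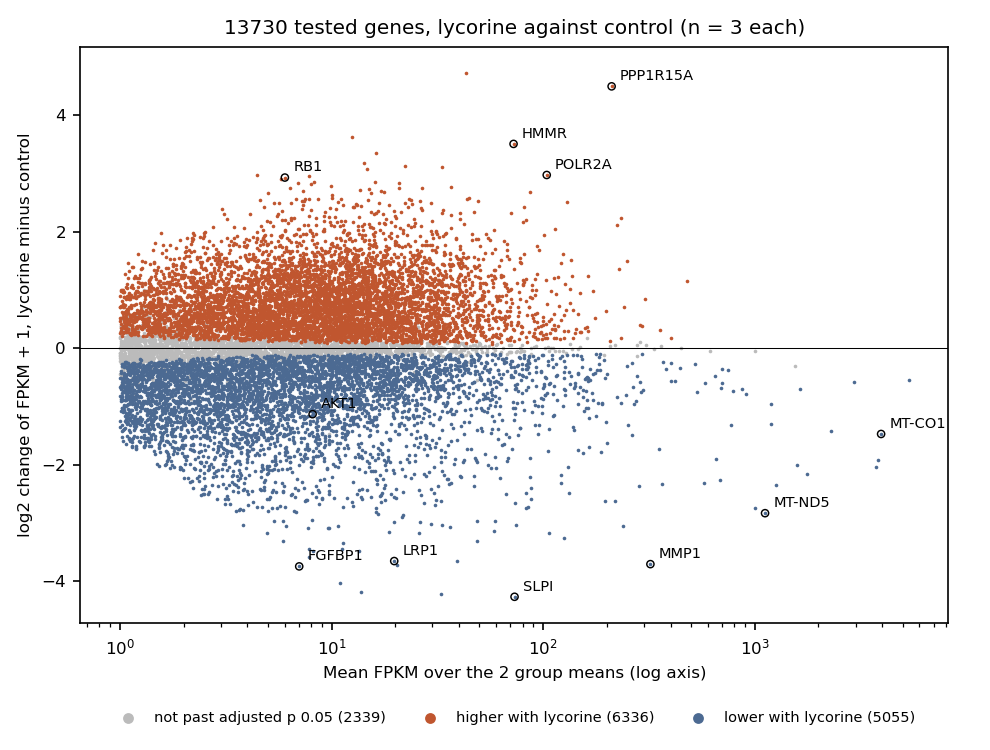
Each point is 1 of the 13730 tested genes, with the mean FPKM of the control and lycorine groups on a log axis (x) and the log2 change of FPKM + 1, lycorine minus control (y), from 3 libraries per group. The 6336 genes that rose and the 5055 that fell at an adjusted p under 0.05 are coloured, and PPP1R15A lies at 4.50 and SLPI at -4.26.

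The largest rise of a protein-coding gene on the log2(FPKM + 1) scale was that of PPP1R15A (ENSG00000087074, chromosome 19, 48872392 to 48876057), which encodes GADD34, the stress-induced subunit that directs a phosphatase to eIF2α. It went from 16.9 ± 1.04 FPKM in control cells to 404 ± 9.78 with lycorine, 23.9-fold (log2 change 4.50, SE 0.05). HMMR, a spindle-associated hyaluronan receptor (chromosome 5, 163460203 to 163491945), rose from 10.9 ± 0.503 to 134 ± 3.42. POLR2A, the largest subunit of RNA polymerase II (chromosome 17, 7484366 to 7514616), rose from 22.7 ± 1.38 to 185 ± 8.45. RB1, the retinoblastoma tumour suppressor (chromosome 13, 48303726 to 48599436), rose from 0.625 ± 0.0146 to 11.4 ± 0.114, and DLX2, a homeobox factor, from 1.22 ± 0.125 to 14.8 ± 1.90. The other genes among the 12 largest rises were the zinc finger genes ZFP30 and ZNF296, the mitochondrial carrier gene SLC25A25, EVC, RNF227, the checkpoint clamp gene RAD9B and WHAMM, with rises between 9.24-fold for WHAMM and 18.4-fold for ZNF296. By limma with Benjamini-Hochberg adjustment, the adjusted p of these 12 lay between 5.26e-09 and 6.16e-08.

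The largest fall on the same scale was that of SLPI, a secreted inhibitor of leukocyte proteases (ENSG00000124107, chromosome 20, 45252239 to 45254564), from 140 ± 7.79 to 6.35 ± 0.466 FPKM (log2 change -4.26, SE 0.06). PI3, another secreted protease inhibitor of the same chromosome, fell from 21.4 ± 0.915 to 1.2 ± 0.0851. MMP1, the interstitial collagenase (chromosome 11, 102789920 to 102798160), fell from 597 ± 4.01 to 45.3 ± 6.96. FGFBP1, a carrier of fibroblast growth factors, fell from 14 ± 1.27 to 0.118 ± 0.0965, a larger ratio of means than that of SLPI, and S100A4, a calcium-binding protein linked to cell motility, from 15.8 ± 0.737 to 0.528 ± 0.271. Genes of the matrix and its receptors were also among the 12 largest falls, with ECM1 at 38.6 ± 0.864 in control cells and 2.02 ± 0.0894 with lycorine, FBLN2 at 15.3 ± 0.642 and 0.355 ± 0.0771, and LRP1 at 37.5 ± 1.68 and 2.07 ± 0.156. FAM167B, CALHM3, ZNF114 and CRIP2 made up the rest. Limma with Benjamini-Hochberg adjustment gave these 12 an adjusted p between 5.26e-09 and 6.41e-08. Exons of SLC25A25, EVC, LRP1 and ZNF114 overlap a gene on the opposite strand (NAIF1, CRMP1, STAT6 and ZNF114-AS1), and reads of the shared bases cannot be told apart without strand. The overlaps covered 6 of 4936, 159 of 7148, 59 of 20839 and 114 of 2993 exonic bases, so only that part of their values is uncertain.

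For the PI3K/AKT question, the kinase genes AKT1 and AKT2 fell while genes upstream and downstream went both ways. AKT1 (ENSG00000142208, chromosome 14, 104769349 to 104795751) went from 11.5 ± 0.486 to 4.74 ± 0.124 FPKM (log2 change -1.13, SE 0.05) and AKT2 (chromosome 19, 40230317 to 40285536) from 9.31 ± 0.448 to 4.05 ± 0.277 (log2 change -1.03, SE 0.06). MTOR (chromosome 1, 11106535 to 11262507) rose from 11.6 ± 0.0691 to 26.6 ± 0.613. PIK3CA, the catalytic subunit p110α, stood at 8.83 ± 0.434 and 11.4 ± 0.337, a rise on the deposited scale that did not pass after quantile normalization or once the trend with gene length and GC content was removed. Further rises were those of the insulin receptor substrate IRS2 (6.03 ± 0.560 to 27.7 ± 0.373), the S6 kinase gene RPS6KB1 (9.92 ± 0.556 to 32.6 ± 1.40) and the AKT phosphatase PHLPP2 (1.62 ± 0.0607 to 7.43 ± 0.0522). The translation repressor EIF4EBP1 fell from 113 ± 2.03 to 39.8 ± 1.27 and the mTOR inhibitor DEPTOR from 11.8 ± 0.431 to 1.27 ± 0.293. Outside the naming rule, the catalytic subunit genes PIK3CB and PIK3CD fell from 15.0 ± 0.0296 to 7.98 ± 0.238 and from 11.5 ± 0.347 to 4.26 ± 0.371. The regulatory subunit gene PIK3R1 rose from 3.86 ± 0.175 to 9.46 ± 0.564. Exon overlaps are not given for these genes.

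As a list, the PI3K/AKT/mTOR components did not move one way. Of 39 tested members 23 rose and 15 fell, or 24 and 15 adjusted over the list alone, with a median log2 change of 0.34, and camera set against the other genes gave an adjusted p of 0.505. Without the filter on low values camera gave the list an adjusted p of 0.0330. It then compared lists with 38093 genes, many too low to change much on the log2(FPKM + 1) scale, and called 23 lists. Such a call does not compare a list with expressed genes alone, here and for the lists below. Fry, which asks only whether the members move on balance one way, gave 1.2e-04 (upward). It called 29 of the 33 lists, since 83.0% of genes passed, and so does not set this list apart. Among genes that FOXO factors, which AKT restrains, are known to activate, 10 of 18 rose and 5 fell, the same counts as adjusted over the list alone (median 0.32, camera adjusted p = 0.218, and adjusted p = 0.0178 without the filter). They included the growth arrest gene GADD45A, from 80.5 ± 3.97 to 384 ± 13.8 FPKM, TRIB1 from 7.66 ± 0.387 to 22.1 ± 0.379 and BCL6 from 8.75 ± 0.224 to 26.2 ± 1.69, while the receptor gene ERBB3 fell from 11.6 ± 0.147 to 4.69 ± 0.585. Transcript levels do not measure the phosphorylation of AKT or FOXO.

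Stemness markers moved apart. ALDH1A1, the aldehyde dehydrogenase used to mark ovarian cancer stem cells (chromosome 9, 72900662 to 73080442), had 215 reads over the 3 control libraries and 0 over the 3 lycorine libraries. Set against a floor of 3 reads over the group, its level was at least 72.0-fold lower with lycorine, a bound that covers counting error only. CD24 fell from 129 ± 4.20 to 84.4 ± 3.62 FPKM and MYC (chromosome 8, 127735434 to 127741434) from 93.9 ± 2.07 to 64.0 ± 2.93. NOTCH3 fell from 12.4 ± 0.528 to 0.940 ± 0.0763 and PROCR, the protein C receptor, from 30.1 ± 1.45 to 4.02 ± 0.253. In the other direction, NOTCH1 rose from 8.67 ± 0.619 to 18.8 ± 1.3, the Wnt receptor FZD7 from 12.5 ± 0.238 to 26.3 ± 0.951, KLF4 from 11.4 ± 0.355 to 15.8 ± 1.29 and the Polycomb gene BMI1 from 6.17 ± 0.364 to 8.69 ± 0.0568. CD44, which overlaps CD44-AS1, stood at 39.6 ± 0.262 and 46.7 ± 2.41, a rise that did not pass after quantile normalization.

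Pluripotency factors were low in both groups. SOX2 stood at 1.62 ± 0.186 FPKM in control cells and 1.98 ± 0.0985 with lycorine, which did not pass limma with Benjamini-Hochberg adjustment (adjusted p = 0.0532). By limma it passed as a rise without control replicate 1 (adjusted p = 0.0267), after quantile normalization (0.0056) and without the trend of variance on mean level (0.0265). POU5F1, which overlaps TCF19 on the opposite strand, had 114 reads over the control libraries and 92 over the lycorine libraries, NANOG 0 and 2, and KIT 6 and 2, below the filter and with no difference detectable at this depth. PROM1, which encodes CD133, had 2, 0 and 7 reads in the control libraries and 0 with lycorine, too few to show a difference, since without control replicate 3 only 2 reads are left (limma without the filter, Benjamini-Hochberg adjusted p = 0.518). Of the 19 tested stemness markers 7 rose and 10 fell, or 8 and 10 adjusted over the list alone (median -0.18). The list did not differ from other genes by camera (adjusted p = 0.351). Fry, which called 29 of the 33 lists, gave 4.9e-05 (downward), and so does not set this list apart. Of the 12 stemness markers under the filter, 3 were called lower and 2 higher without it. The drug efflux gene ABCB1, also in this list, stood at 754 ± 4.54 and 541 ± 13.8, a fall that turned into a rise of 0.36 on the log2 scale under quantile normalization. The labels name A2780 and no drug-selected subline, and the identity of the line was not checked here.

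**Figure D2:**
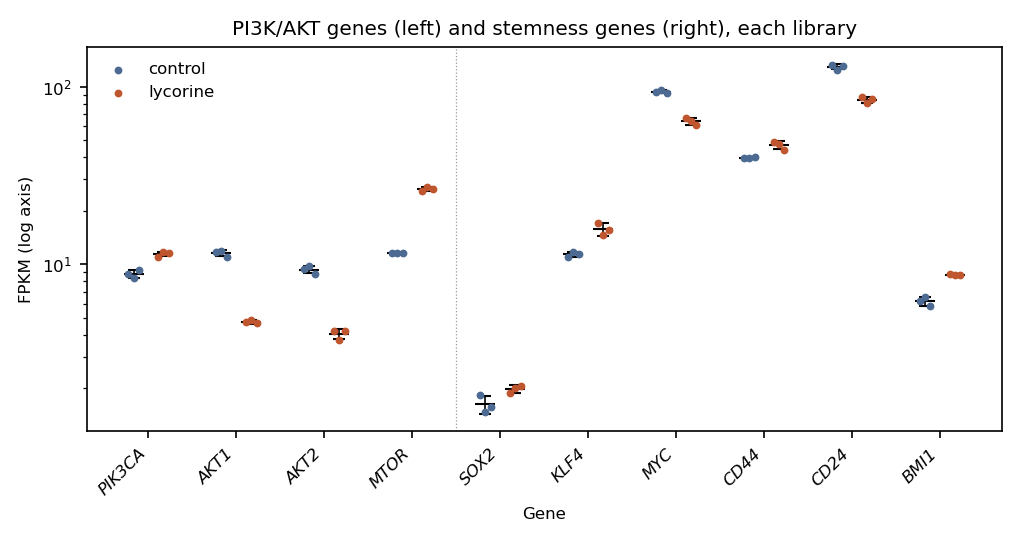
FPKM on a log axis (y) of 4 PI3K/AKT genes and 6 stemness genes (x), with 1 point per library and the mean ± SD of 3 libraries in black. AKT1 and AKT2 are lower with lycorine and MTOR higher, CD24 and MYC are lower, and SOX2 did not pass the test.

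Of the targets of the pathways tied to stemness, 7 of the 13 in each list lay under the filter. Of 6 tested Wnt targets 3 rose and 3 fell, as they did adjusted over the list alone (median -0.02, camera adjusted p = 0.776). Of the 7 Wnt targets under the filter, limma without the filter called 5 lower and 1 higher with Benjamini-Hochberg adjustment, among them NKD1 at 1.07 ± 0.0324 and 0.204 ± 0.0395 FPKM and NOTUM at 1.03 ± 0.145 and 0.0722 ± 0.0242, named after their values were seen, and the median of all 13 was -0.33 (camera adjusted p = 0.269). The Wnt antagonist DKK1 fell from 17.5 ± 0.636 to 6.88 ± 0.827 FPKM, and ZNRF3, which removes Wnt receptors, rose from 2.91 ± 0.0831 to 8.16 ± 0.765. AXIN2 stood at 1.5 ± 0.167 and 0.991 ± 0.0279, and its fall did not pass after quantile normalization. CCND1, which encodes cyclin D1 and overlaps LTO1, rose from 85.6 ± 3.20 to 113 ± 4.32. Of 6 Notch and Hedgehog targets 3 rose and 3 fell, again also adjusted over the list alone (camera adjusted p = 0.857), with a median of -0.07 and a mean of 0.02 that differed in sign. Of the 7 under the filter 4 were called lower and 1 higher without it, among them the Hedgehog effector GLI1 at 0.691 ± 0.0303 and 0.0316 ± 0.0159, also named after its values were seen, and the median of all 13 was -0.44 (camera adjusted p = 0.512). HES1 rose from 5.31 ± 0.905 to 18.3 ± 0.564 and NRARP from 7.22 ± 0.464 to 30.3 ± 1.82, and HEYL fell from 2.59 ± 0.280 to 1.54 ± 0.0369. HES4 stood at 27.8 ± 2.51 and 20.3 ± 2.84, and its change turned to 0.08 on the log2 scale, not past the threshold, once the trend with length and GC content was removed.

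Mitotic genes rose nearly as a body. Of 39 tested G2/M and mitosis genes 38 rose, 26 of them at least 2-fold, with a median log2 change of 1.2. Survivin (BIRC5) went from 22.8 ± 0.303 to 87.3 ± 0.303 FPKM, the proliferation marker MKI67 from 20.6 ± 0.566 to 62.7 ± 2.92, the condensin gene NCAPG from 13.6 ± 0.316 to 67.0 ± 1.86 and the chromokinesin KIF4A from 9.83 ± 0.254 to 36.4 ± 0.460. The phosphatase gene CDC25B alone did not rise, at 50.6 ± 2.7 and 47.1 ± 0.529 (limma with Benjamini-Hochberg, adjusted p = 0.0542). CDC25B passed as a fall adjusted over the list alone, where the counts were 38 and 1, and without control replicate 3 (adjusted p = 0.0136), and turned into a rise of 0.10 once the length and GC trend was removed. Camera called the list (adjusted p = 2.44e-09), a call lost with the correlation estimated from the data (adjusted p = 0.193 with an estimated correlation). NCAPG and KIF4A overlap LCORL and PDZD11 on the opposite strand.

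Other cell cycle lists had more members that rose than fell, and camera called them under some settings only. For G1/S and DNA replication, 28 of 40 members rose and 10 fell, also adjusted over the list alone (median 0.43, camera adjusted p = 0.0800). CDC25A, the phosphatase that activates CDK2, rose from 4.63 ± 0.310 to 37.1 ± 0.438 FPKM and E2F2 from 1.69 ± 0.0980 to 8.38 ± 0.0692, while DNA ligase I (LIG1) fell from 7.03 ± 0.274 to 2.04 ± 0.0812. Among G1 cyclins, CDKs and their inhibitors, 13 of 17 rose and 3 fell, likewise adjusted over the list alone (median 0.73, camera adjusted p = 0.0610). CDKN1A, the inhibitor p21 (chromosome 6, 36676460 to 36687339), rose from 26.3 ± 1.51 to 48.4 ± 1.24, CDKN1B, which encodes p27, from 13.4 ± 0.768 to 29.96 ± 0.448, and RBL1 from 3.37 ± 0.512 to 18.8 ± 0.803. CDKN2A fell from 74.6 ± 4.73 to 34.5 ± 2.36 and RBL2, which overlaps AKTIP, from 14.6 ± 0.505 to 3.81 ± 0.149. Homologous recombination and Fanconi genes rose in 16 of 23 cases and fell in 5, also adjusted over the list alone (median 0.60, camera adjusted p = 0.0800), with BRCA2 at 1.5 ± 0.0923 and 5.56 ± 0.243 and PALB2 at 3.31 ± 0.141 and 11.2 ± 0.358. Of 6 tested replication-dependent histone genes 5 rose and 0 fell by either adjustment, that adjusted over the list alone included (median 1.04, camera adjusted p = 0.136), among them HIST1H2BK from 17.7 ± 0.596 to 29.9 ± 1.08. These mRNAs mostly lack poly(A) tails, and 20 of the 26 members were below the filter. Without the filter on low values camera called the G1/S list and the G1 cyclin list (adjusted p = 1.1e-04 for each), the recombination list (3.0e-04) and the histone list (0.0168). The background then holds many low genes that can change little on this scale, and 23 lists were called. These calls therefore do not compare the lists with expressed genes alone. Once the length and GC trend was removed it called the G1/S list (adjusted p = 0.0454) and the G1 cyclin list (0.0235). With an estimated correlation, camera gave adjusted p = 0.424 for the G1/S list, 0.401 for the G1 cyclin list, 0.295 for the recombination list and 0.424 for the histone list.

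Genes that p53 activates rose on balance. Of 25 tested, 19 rose and 6 fell, the same counts as adjusted over the list alone (median 0.74, camera adjusted p = 0.0191, and adjusted p = 0.327 with an estimated correlation). The antiproliferative gene BTG2 rose from 4.03 ± 0.0644 to 23.0 ± 0.870 FPKM, SERTAD1 from 6.27 ± 0.563 to 41.2 ± 2.29 and the kinase gene PLK3 from 4.89 ± 0.264 to 18.5 ± 0.431. BTG2 and PLK3 are also known as immediate early genes. Among the members that fell were CCNG1 at 88.3 ± 2.62 and 21.4 ± 1.71 and FDXR at 9.25 ± 0.686 and 3.72 ± 0.0454. In the BCL2 family and the caspases, 18 of 27 rose and 8 fell, also adjusted over the list alone (median 0.49, camera adjusted p = 0.136, and adjusted p = 7.9e-04 without the filter). Pro-apoptotic genes went both ways. PMAIP1 (NOXA) and BAK1 rose from 32.2 ± 0.717 to 77.6 ± 2.89 and from 17.4 ± 0.894 to 39.5 ± 1.11, and CYCS, cytochrome c, rose from 50.5 ± 1.48 to 109 ± 2.74. BID fell from 6.51 ± 0.139 to 3.48 ± 0.340. Outside the naming rule, BAX fell from 19.8 ± 0.501 to 15.1 ± 1.29 and BBC3 from 3.09 ± 0.331 to 2.18 ± 0.471. BCL2L11 (BIM), a member of the FOXO list, rose from 3.73 ± 0.412 to 13.2 ± 0.675. Of the survival genes, BCL2L1 fell from 30.8 ± 0.485 to 10.5 ± 0.922, with exons that overlap ABALON, and BCL2 rose from 1.10 ± 0.0622 to 1.96 ± 0.115. MCL1 stood at 48.9 ± 1.21 and 47.6 ± 1.08 (limma with Benjamini-Hochberg, adjusted p = 0.344), and under median-ratio scaling its change was -0.16 with an adjusted p of 0.00157. It also passed as a fall after quantile normalization (-0.20, adjusted p = 5.8e-04) and with protein-coding genes alone. The same held with the library total over nuclear genes, with the length and GC trend removed and by limma-voom.

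Stress response genes split into some that rose steeply and a larger number that fell. ATF4, the transcription factor of the integrated stress response (chromosome 22, 39519695 to 39522685), rose from 128 ± 2.19 to 330 ± 17.9 FPKM, ATF3 from 4.38 ± 0.167 to 26.3 ± 0.745 and DDIT3 (CHOP), which overlaps MARS and MBD6, from 25.7 ± 0.775 to 42.2 ± 3.28. Other genes that ATF4 is known to induce fell, with PSAT1 at 141 ± 1.62 and 24.5 ± 1.49, PHGDH at 17.8 ± 0.430 and 5.40 ± 0.163, the cystine transporter SLC7A11 at 35.9 ± 1.85 and 3.66 ± 0.508, and CHAC1 at 12 ± 0.483 and 2.94 ± 0.321. In all, 13 of 33 members of the ATF4 list rose and 17 fell, likewise adjusted over the list alone (median -0.39, camera adjusted p = 0.306). The direction was downward by camera and the median and upward by fry, which did not call the list either (adjusted p = 0.399). Chaperones of the unfolded protein response fell in 12 of 20 cases and rose in 5, also adjusted over the list alone (median -0.35, camera adjusted p = 0.0191, and adjusted p = 0.295 with an estimated correlation). PDIA6 fell from 68.1 ± 1.51 to 14 ± 0.721, PDIA4 from 137 ± 3.78 to 36.8 ± 1.41 and HSP90B1 (GRP94), which overlaps C12orf73, from 303 ± 1.80 to 98.2 ± 3.39, whereas XBP1 rose from 23.2 ± 1.15 to 37.5 ± 3.01. Of 15 heat shock genes 11 fell and 4 rose by either adjustment, that adjusted over the list alone included (median -0.34, camera adjusted p = 0.0610). Camera called this list without the filter (adjusted p = 0.0307), with a minimum mean FPKM of 5 (0.0212), once the length and GC trend was removed (0.0372) and by limma-voom (0.0441). It did not call the list with an estimated correlation (adjusted p = 0.295). HSPA8, the constitutive HSP70 with many processed pseudogenes, fell from 227 ± 3.14 to 23.0 ± 1.55, and BAG3 rose from 11.1 ± 0.750 to 17.9 ± 0.434.

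Transcripts degraded by nonsense-mediated decay rose together. Of 18 tested members 17 rose, 13 of them at least 2-fold, and 0 fell, or 18 and 0 adjusted over the list alone (median 1.44, camera adjusted p = 2.39e-05, and adjusted p = 0.193 with an estimated correlation). The snoRNA host gene SNHG15 rose from 4.36 ± 0.25 to 37.5 ± 1.3 FPKM, SNHG1 from 28.7 ± 0.0852 to 132 ± 7.45 and uridine phosphorylase UPP1 from 7.0 ± 0.405 to 45.2 ± 0.610. Immediate early genes rose in 17 of 25 cases and fell in 7, also adjusted over the list alone (median 0.49, camera adjusted p = 0.265, and adjusted p = 0.00511 without the filter). KLF10 rose from 11.9 ± 0.0454 to 75.4 ± 3.22 and the AP-1 gene FOSL1 from 131 ± 6.0 to 369 ± 4.48. CYR61 and CTGF, secreted proteins that YAP is known to induce, fell from 378 ± 7.02 to 60.5 ± 2.34 and from 337 ± 4.48 to 53.8 ± 2.25.

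The protein synthesis machinery moved in opposite directions. Ribosome biogenesis genes rose in 25 of 31 cases and fell in 4, also adjusted over the list alone (median 0.99, camera adjusted p = 2.46e-04, and adjusted p = 0.355 with an estimated correlation). The snoRNP genes NOP56 and NOP58 rose from 31.2 ± 0.179 to 103 ± 2.66 FPKM and from 23.7 ± 0.780 to 88.9 ± 2.38, and UTP20 rose from 7.65 ± 0.0871 to 24.9 ± 0.514. Cytosolic ribosomal proteins fell in 54 of 76 cases and rose in 7, by both the adjustment over all genes and that adjusted over the list alone (median -0.31, camera adjusted p = 3.09e-06, and adjusted p = 0.466 with an estimated correlation). RPL31 fell from 156 ± 4.26 to 70.2 ± 4.29, while RPL10A rose from 298 ± 7.30 to 662 ± 26.9. After quantile normalization the ribosomal protein list was no longer called (median -0.20, adjusted p = 0.0728), and ribosomal protein genes share reads with many processed pseudogenes. Of 29 translation factors 16 rose and 10 fell, likewise adjusted over the list alone (median 0.23, camera adjusted p = 0.505), with EIF1 at 69.3 ± 1.22 and 200.01 ± 6.10, EIF5 at 32.5 ± 0.531 and 94.4 ± 2.79 and the elongation factor EEF1A1, which also has processed pseudogenes, at 3334 ± 26.9 and 1251 ± 70.6. The log2 change of EEF1A1 went from -1.41 to -0.20 under quantile normalization, and that of RPL10A from 1.15 to 2.03.

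All 13 mRNAs encoded by the mitochondrial genome fell on the deposited scale, 10 of them at least 2-fold, and all 13 also adjusted over the list alone, whereas after quantile normalization 9 fell and 4 rose (MT-CO1, MT-ND1, MT-ND2 and MT-CYB, by up to 0.34 on the log2 scale). MT-CO2 went from 5988 ± 229 to 1455 ± 37.7 FPKM and MT-ND5 from 1962 ± 135 to 275 ± 11.4 (log2 change -2.83, SE 0.06). MT-ATP6 fell from 2115 ± 130 to 415 ± 14.1, and MT-ATP6 and MT-ND4L share bases with neighbouring genes of the same strand. Under quantile normalization the log2 changes were smaller, at -0.69 for MT-CO2, -1.95 for MT-ND5 and -1.42 for MT-ATP6. Under each other alternative fitted per gene all 13 fell. The list median was -2.04 (camera adjusted p = 2.10e-06, and adjusted p = 0.295 with an estimated correlation), and after quantile normalization the list was not called (median -0.95, adjusted p = 0.0751). Nuclear-encoded respiratory chain genes did not follow, with 12 of 30 higher and 10 lower, also adjusted over the list alone, and a median of 0.03 beside a mean of -0.0058 and a downward camera direction (adjusted p = 0.639). COX6C fell from 32.9 ± 1.37 to 13.8 ± 1.23.

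Lipid synthesis genes fell. Of 24 tested cholesterol synthesis genes 20 fell and 3 rose, also adjusted over the list alone (median -0.65, camera adjusted p = 2.02e-04, and adjusted p = 0.295 with an estimated correlation). Squalene synthase (FDFT1) fell from 31.4 ± 0.258 to 4.35 ± 0.354 FPKM and the sterol sensor INSIG1 from 24.5 ± 1.57 to 3.26 ± 0.220. Of 12 fatty acid synthesis genes 11 fell and 0 rose, by either adjustment, that adjusted over the list alone included (median -0.83, camera adjusted p = 2.46e-04, and adjusted p = 0.295 with an estimated correlation). SCD, the stearoyl-CoA desaturase, fell from 103 ± 0.852 to 21.3 ± 0.656, fatty acid synthase (FASN) from 83.0 ± 4.84 to 34.2 ± 1.03 and ACLY from 73.7 ± 1.67 to 35.7 ± 0.427. The elongase ELOVL6 stood at 5.89 ± 0.544 and 6.05 ± 0.241, and once the length and GC trend was removed it passed as a fall of -0.21.

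Glycolysis and hypoxia genes went both ways, with 9 of 24 higher and 12 lower, also adjusted over the list alone (median -0.08, mean 0.01, camera direction down with adjusted p = 0.306). PGK1, which overlaps ATP7A, fell from 61.0 ± 1.49 to 29.3 ± 0.971 FPKM, while hexokinase HK2 rose from 4.22 ± 0.0664 to 13.8 ± 0.325 and adrenomedullin (ADM) from 5.47 ± 0.242 to 26.1 ± 1.24. NRF2 and antioxidant genes fell in 15 of 25 cases and rose in 5, likewise adjusted over the list alone (median -0.56, camera adjusted p = 0.00794, and adjusted p = 0.295 with an estimated correlation). NQO1 fell from 55.6 ± 1.01 to 17.8 ± 1.13, PRDX1, which overlaps MMACHC, from 226 ± 1.33 to 66.9 ± 1.45 and ferritin heavy chain FTH1, with processed pseudogenes, from 606 ± 42.0 to 120.3 ± 5.09, whereas HMOX1 rose from 8.44 ± 0.775 to 16.1 ± 0.461. Of 11 ferroptosis and iron genes 6 fell and 4 rose, also adjusted over the list alone (median -0.45, camera adjusted p = 0.265), among them NCOA4, the receptor for ferritin turnover, which rose from 20.7 ± 0.659 to 45.4 ± 1.31. The ferritin light chain FTL stood at 2008 ± 37.1 and 1246 ± 58.2, a fall that turned into a rise of 0.65 on the log2 scale under quantile normalization. Autophagy and lysosome genes rose in 12 of 26 cases and fell in 10, also adjusted over the list alone (median 0.05, camera adjusted p = 0.976). The sialidase NEU1 rose from 29.7 ± 1.04 to 105 ± 3.22 and MAP1LC3B, which overlaps FBXO31, from 21.8 ± 1.07 to 44.1 ± 1.58, and the cathepsins CTSB and CTSD fell from 151 ± 3.66 to 24.3 ± 0.475 and from 17 ± 0.918 to 5.87 ± 0.381.

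Lineage markers of the ovarian epithelium fell. Of 10 tested, 7 fell, each at least 2-fold, and 2 rose, also adjusted over the list alone (median -2.19, camera adjusted p = 0.00829, and adjusted p = 0.381 with an estimated correlation). PAX8, a transcription factor of Müllerian epithelium, fell from 59.0 ± 3.20 to 11.7 ± 0.120 FPKM, and the keratins KRT18, KRT8 and KRT7 fell from 193 ± 4.56 to 20.7 ± 1.83, from 203 ± 6.15 to 40.4 ± 0.999 and from 67.1 ± 2.55 to 14 ± 0.394. PAX8 and KRT7 overlap antisense genes, and KRT8 and KRT18 overlap each other on opposite strands. WT1 rose from 0.814 ± 0.135 to 2.28 ± 0.0758. FOXL2 stood at 2.74 ± 0.447 and 3.68 ± 0.502, a rise no longer called by limma with Benjamini-Hochberg adjustment without control replicate 2 (adjusted p = 0.0724), control replicate 3 (0.0718) or lycorine replicate 1 (0.0746).

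Epithelial and mesenchymal genes, tested as one list, fell in 16 of 25 cases and rose in 7, also adjusted over the list alone (median -0.45, camera adjusted p = 0.0128, and adjusted p = 0.295 with an estimated correlation). The members with the clearest falls encode matrix and adhesion proteins, with fibronectin (FN1) at 424 ± 10.0 and 50.5 ± 2.17 FPKM, SPARC at 139 ± 1.47 and 49.6 ± 1.57, and integrin β1 (ITGB1), which overlaps ITGB1-DT, at 112 ± 1.40 and 43.0 ± 0.418. The transcription factors ZEB2 and SNAI1, known as repressors of epithelial genes, rose from 1.97 ± 0.0276 to 8.86 ± 0.150 and from 9.68 ± 0.247 to 30.7 ± 1.89. Markers of fibroblasts were measured in these cells and moved the same way as the matrix genes, with all 4 tested members lower, also adjusted over the list alone. LUM fell from 18 ± 0.672 to 1.25 ± 0.313, FBLN1 from 12 ± 0.448 to 1.74 ± 0.0273, PDGFRB from 3.80 ± 0.0281 to 0.519 ± 0.0336 and COL1A1 from 55.3 ± 3.20 to 30.9 ± 1.66. Of the immune markers 2 passed the filter, HLA-DRA, which fell from 4.95 ± 1.12 to 0.0369 ± 0.0463, and ITGAM, which rose from 0.594 ± 0.0869 to 1.67 ± 0.101, 1 in each direction also adjusted over the list alone. Of the endothelial markers 2 passed as well, TIE1, which fell from 1.87 ± 0.0211 to 0.130 ± 0.0573, and ESAM, at 8.35 ± 0.330 and 10.8 ± 0.542, 1 in each direction also adjusted over the list alone, the latter not called after quantile normalization. These 3 lists had too few tested members for camera. Of their members under the filter, limma without the filter called 2 immune, 5 endothelial and 2 fibroblast markers lower, of 13, 8 and 7.

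NF-κB and interferon genes went both ways. Of 17 NF-κB and inflammatory genes 9 rose and 6 fell, also adjusted over the list alone (median 0.30, camera adjusted p = 0.505), with rises of NFKB1 from 8.16 ± 0.194 to 32.0 ± 0.554 FPKM, TNFAIP3 from 20.3 ± 0.683 to 60.9 ± 1.42 and the cytokine LIF from 3.91 ± 0.363 to 19.0 ± 0.369. The chemokine CXCL8 fell from 80.1 ± 4.67 to 43.8 ± 2.73 and ICAM1 from 103 ± 3.19 to 62.9 ± 1.70. Interferon-stimulated genes rose in 8 of 18 cases and fell in 9, also adjusted over the list alone (median -0.06, camera adjusted p = 0.505), and of 5 more under the filter 4 were called lower without it. BST2 (tetherin) fell from 134 ± 3.11 to 15.5 ± 0.517 and IFIT1 from 42.4 ± 2.13 to 12.1 ± 1.01, while the RNA sensor IFIH1 rose from 5.97 ± 0.224 to 29.7 ± 1.94 and RSAD2 from 1.23 ± 0.150 to 10.4 ± 0.712. Of 10 drug efflux transporters 5 fell and 2 rose, also adjusted over the list alone (median -0.12, camera adjusted p = 0.265), among them ABCC1, from 32.9 ± 0.758 to 24.3 ± 0.878, and the copper transporter ATP7B, from 2.02 ± 0.0605 to 0.403 ± 0.0551.

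Of 33 lists with at least 5 tested members, camera with a preset correlation of 0.01 called 12 at an adjusted p under 0.05, 4 of them higher and 8 lower with lycorine. None of the 12 passed with the correlation estimated per list, where camera called 0 lists and 4 had an unadjusted p under 0.05, while fry called 29. Other divisions of the 6 libraries into 3 and 3 gave between 6 and 11 called lists by the same preset, but each keeps a part of the difference between the groups and so is no null. In the simulated data, where genes were drawn independently, camera called 0 of 30 lists of unchanged genes.

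**Figure D3:**
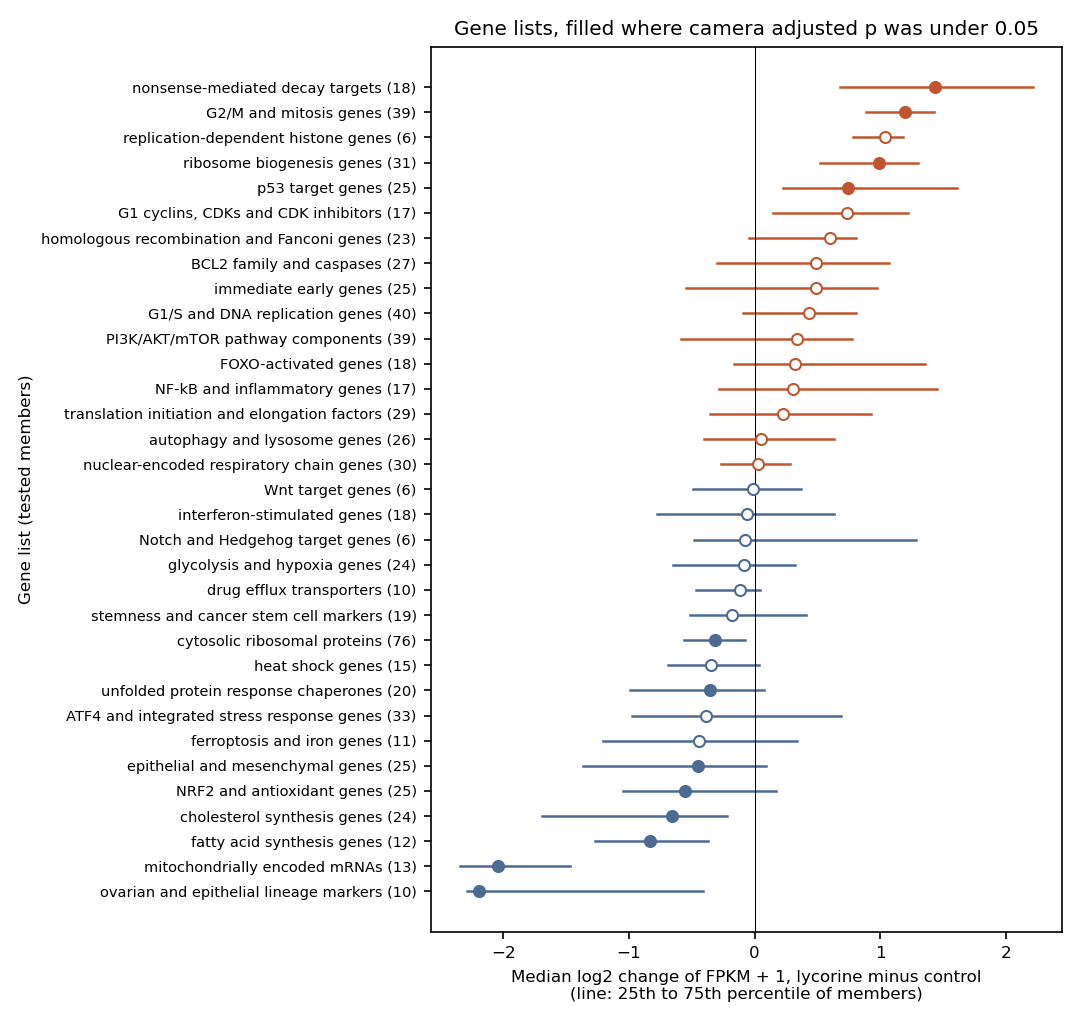
Median log2 change of FPKM + 1, lycorine minus control (x), of the tested members of 33 gene lists (y, with the number of tested members), with lines from the 25th to the 75th percentile of members. Filled points mark the 12 lists that camera called with a preset correlation, from -2.19 for the lineage markers and -2.04 for the mitochondrially encoded mRNAs to 1.2 for the G2/M genes and 1.44 for the decay targets.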

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

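Limma-voom, the library total over nuclear genes and the removal of the length and GC trend were chosen after the data had been seen, and the other alternatives before. Of 3700 values of named genes under the alternatives 3666 kept their direction and their side of the threshold, and of 623 values of lists 578 did. With a mean FPKM of at least 5, where fewer genes were tested, 7041 genes passed, 2207 of them at least 2-fold, with 797 lower. Camera called 23 lists without the filter, where many low genes that can change little on this scale joined the background. It called 0 with an estimated correlation, where 4 had an unadjusted p under 0.05. Fry, which asks another question, called 29 of the 33 lists. The PI3K/AKT/mTOR list passed without the filter (median 0.33). By fry it passed upward (adjusted p = 1.2e-04) and the stemness list downward (4.9e-05). Since nearly all lists passed by fry, this sets neither of them apart. Quantile normalization reversed ABCB1 to 0.36 and FTL to 0.65. Both are abundant, with ABCB1 at rank 28 and FTL at 2008 FPKM in control cells. Quantile normalization gives equal ranks equal values, so smaller falls of such genes are partly built in. Removal of the length and GC trend turned HES4 to 0.0841, CDC25B to 0.10 and ELOVL6 to -0.21. Except for the filter at 5, the cause was not tested. Leaving out each library in turn gave 11077 to 11138 genes past the threshold, 3536 to 3594 at least 2-fold, 1894 to 1918 higher and 1625 to 1694 lower, and 12 lists each time. With the replicate number as a block, 11282 genes passed, 3556 of them at least 2-fold, and 12 lists were called. Libraries of the same number deviated from their group means with correlations of 0.005, 0.004 and -0.029 across genes, so the numbers do not pair the samples. Limma-voom on the recovered reads called 11513 genes, 11086 of them also called by limma on log2(FPKM + 1) in the same direction. In simulated data with no change in most genes, 8.12% to 15.3% of limma's calls on log2(FPKM + 1) were wrong, 8 of 16 and 21 of 31 of them in genes under 1000 bases. These shares include a small shift between groups that the library totals built into the simulations. Only 200 of the 13730 simulated genes were changed, whereas 83.0% of the real genes were called. The shares are therefore no error rate for the real calls. Single calls of short genes with small changes are the least secure.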

Other observations

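The tests of the mitochondrial mRNAs against normalization and against loss of mitochondrial RNA as a whole, and those of the G2/M genes against scaling and against more cells in cycle, were chosen after the result was seen, as were the genes named in this part.

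Of 444 tested C2H2 genes 317 rose and 73 fell (limma with Benjamini-Hochberg adjustment), 132 and 19 of them at least 2-fold, with a median log2 change of 0.64. That median was between 0.43 and 0.87 under every alternative run. Of 557 genes of other families 341 rose and 146 fell, with a median of 0.35, which lay between 0.04 without the filter and 0.43 over the alternatives, and no test set them against all genes. The bHLH family went both ways, with 22 of 49 higher and 21 lower. ARID genes, which bind AT-rich DNA, rose in 12 of 13 cases and the E2F family of cell cycle regulators in 8 of 10, while nuclear receptors of the THR-like family rose in 4 of 14 and fell in 7. Long non-coding RNAs went both ways. PVT1, a neighbour of MYC, rose from 5.01 ± 0.39 to 25.2 ± 0.186 FPKM, whereas NEAT1, the scaffold of paraspeckles, fell from 47.3 ± 6.95 to 5.15 ± 1.28 and MALAT1 from 84.4 ± 37.3 to 22.1 ± 3.17. Of 15 tested SNHG genes outside the list of decay targets 5 rose and 8 fell. SNHG8 rose from 37.9 ± 1.66 to 221 ± 21.5 and SNHG17 from 4.34 ± 0.200 to 29.2 ± 1.24, while SNHG3, which overlaps RCC1, fell from 12.3 ± 1.04 to 3.94 ± 0.324.

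HRK, a pro-apoptotic BH3-only gene, rose from 0.147 ± 0.0313 to 2.71 ± 0.263 FPKM, and INHBE, an inhibin subunit gene, fell from 9.69 ± 0.555 to 0.183 ± 0.0925. ACTB, often used as a reference gene, fell from 1039 ± 40.8 to 279 ± 12.3. ABCB1 (chromosome 7, 87503633 to 87713323) ranked 28 of all genes of the table in control cells at 754 ± 4.54, against 41.9 ± 0.580 for its neighbour ABCB4. Drug-selected sublines of A2780 exist, the labels name none, and the identity of the line was not checked, so levels of ABCB1 and other efflux genes hold for the cells as labelled.

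The mitochondrial mRNAs fell by a median of -2.04. Under quantile normalization the median was -0.95 (95% interval -1.62 to 0.0957), 4 of the 13 rose and the list was not called (camera adjusted p = 0.0751). All 13 fell in every other setting, median ratios and limma-voom included. Quantile normalization gives equal ranks equal values in all libraries, and MT-RNR2 and MT-RNR1 ranked 1 and 5 in control cells. Smaller changes of such abundant transcripts are partly built in there, so the test cannot decide on scaling, which stays open as a cause. The 2 mitochondrial rRNAs fell by less, with a mean of -0.56 and a difference from the mRNAs of 1.48 (0.908 to 1.79), although MT-RNR1 rose by 0.72 under quantile normalization. The RNA was taken with oligo-dT beads, and how well these rRNAs are captured that way was not examined. Loss of mitochondrial RNA as a whole predicted a difference within 0.5, which the interval excludes, though it does not clear the bound of 1 set against it. The mRNAs also differed among themselves, from -0.73 for MT-CYB to -2.83 for MT-ND5 (25th to 75th percentile -2.35 to -1.47). These values argue against an equal loss of all mitochondrial RNA on the deposited scale. A loss that differs between transcripts stays open. A higher share of nuclear RNA predicted that nuclear RNAs rise together, with a median above 1. Of the 3 tested, MALAT1 and NEAT1 fell and PVT1 rose (median -1.81, -2.98 to 2.13). KCNQ1OT1 stood at 0.797 and 0.344 FPKM and FTX at 0.505 and 0.213, both below the filter. With 3 values the interval is only their lowest and highest, so it cannot decide, and this explanation also stays open. The capture of these nuclear RNAs by oligo-dT beads was not examined either.

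The G2/M genes rose by a median of 1.2, and the median was 1.08 (0.850 to 1.26) after the length and GC trend was removed and 1.07 (0.878 to 1.23) under median-ratio scaling, with 1.08 under quantile normalization. The first of these values argues against that trend as the whole cause. The rise kept about its size under both scalings. Median ratios move all genes of a library alike, and took the median of all genes only from 0.09 to -0.01. They could not bring 1.2 below the 0.25 set for scaling, so that test does not decide on scaling. The G2/M genes rose more than the G1/S genes, by a difference of medians of 0.77 (0.489 to 1.14, permutation p = 1e-05, the smallest these permutations can give). A larger share of cells in cycle predicted less than 0.25, but the interval reaches below the bound of 0.5 set against it, and it stays open. An effect of lycorine on the cell cycle stays open and untested, since DNA content and the mitotic index were not analysed here.

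For the C2H2 genes, the median stayed 0.48 (0.387 to 0.545) above that of all genes after the length and GC trend was removed, against 0.55 before, which argues against that trend as the whole cause. Their median was higher than that of the other families pooled by 0.29 (0.192 to 0.406, permutation p = 1e-04, the smallest these permutations can give). Single families reached the C2H2 median of 0.64 or passed it, with 0.82 for RHD, 0.77 for ZBTB, 0.74 for E2F, 0.70 for ARID and 0.64 for MYB genes. Others were lower, with bHLH at 0.15 and THR-like at -0.21 among them. Since the pooled difference of 0.29 lies under the bound of 0.3 set before it was seen, a rise of transcription factors as a class stays open for a part of the pattern.

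A further hypothesis was that decay targets rise because they are stabilised, so that SNHG genes outside the list would rise as well. Their median differed from that of other long non-coding genes by -0.26 (-0.960 to 0.553; permutation p = 0.39), which does not decide it.

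The rule for reading these 9 tests was changed after their values had been seen, and the counts here are for the tests as given above. A test of the mitochondrial mRNAs with the library total over nuclear genes was replaced by the one with quantile normalization, since a falling mitochondrial share lets it only deepen the fall. The rule tried first read the value alone and counts 7 explanations as argued against. It was replaced by the one used here, in which the whole 95% interval must lie beyond the bound, and which leaves 3 argued against and 6 open. A rule between them, tried last and not kept, asked that the value pass the bound and that the interval exclude what the explanation predicted. It counts 5, adding loss of mitochondrial RNA as a whole and a larger share of cells in cycle. Apart from these counts, the values above are read as arguing against an equal loss of all mitochondrial RNA. All 3 rules count scaling as argued against for the G2/M genes. That test could hardly have come out otherwise, and it is not read so here. The intervals resample genes, which are not independent, and so are likely too narrow, also for the value of 1.08 of the G2/M genes. The permutation tests exchange genes between sets, so their p-values are likely too small for the same reason.

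The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, the 1 with the most calls for each count, gave 11391 genes, 3554 of them at least 2-fold, and 12 lists. The highest of the others were 0 genes by limma, with at most 56 at an unadjusted p under 0.05, 0 at least 2-fold, and 11 lists. Since the other splits called between 6 and 11 lists, the number of lists sets the real split apart by little. Each of them sets 2 libraries of a group with 1 of the other, and so still holds a part of the difference between groups and is no null for the lists.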
